A study of Mus musculus with 9 samples.

How the data were processed

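Poly(A) selection and the strand setting are not given in the sources used here. RNA from D2A1-d cells was extracted with an automated kit including DNase and sequenced on a BGISEQ-500 instrument, per the labels' protocols. Reads were aligned with STAR and counted per gene with HTSeq on mm10 (GRCm38), per the submitters' processing notes, which give no version or annotation release. The deposited values are whole-number read counts per gene, not normalised, in 1 file per library. Each file ends in 5 summary lines that name no gene, which were left out of library sizes and tests.

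Libraries held 7572114 to 8582235 reads assigned to genes. Of all records in the files, reads assigned to no gene made up 49.5 to 51.6%, alignments to several places 10.5 to 11.6% and reads ambiguous between genes 0.863 to 0.951%. For 107 genes covered over at least 95% by exons of a protein-coding gene on the other strand (at least 500 reads per kb), reads per kb were a median of 1.59 times those of the partner. Reads of a gene and its antisense partner are therefore not told apart here. Alignments to several places were not counted, so near-identical paralogs and mitochondrial genes with nuclear copies are uncertain. Molecular identifiers are not mentioned in the sources used here, so the precision given by depth covers counting error only.

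Of 55335 gene identifiers, 55154 matched a symbol in the reference table of gene names by identifier without version. Coordinates were taken from GENCODE M21 on GRCm38, the build named by the submitters. Libraries were grouped by the labels into NTC, shMed4 #1 and shMed4 #4, with 3 each. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 1.53 to 2.95 over genes with at least 20 reads), so each counted as its own replicate.

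Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 14335 genes, and TMM factors ranged from 0.969 to 1.03. A single model with the 3 groups was fitted by quasi-likelihood (glmQLFit, glmQLFTest). Contrasts were each hairpin minus NTC, the mean of both hairpins minus NTC, and shMed4 #4 minus shMed4 #1. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Values per group are means of CPM with TMM factors, with SD over 3 libraries. The common biological coefficient of variation was 0.0433.

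A total of 29 gene lists, the rule for named genes and the model were fixed before the data were examined. The lists held 823 different genes, of which 669 were measured. They covered Mediator subunits, matrix structure and remodelling, integrins, mesenchymal and epithelial genes, TGF-beta, BMP, YAP and TAZ, immediate-early genes, mitosis, DNA replication, p53 and CDK inhibitors and dormancy-associated factors. They also covered interferon-stimulated genes, cytokines, MHC class I, cholesterol synthesis, the unfolded protein response, hypoxia and glycolysis, heterochromatin factors, nuclear and mitochondrial respiratory genes, ribosomal proteins and histones. The last held markers of leukocytes, endothelium, fibroblasts and mammary lineages. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 29 lists. An estimated correlation and fry were the alternatives. Families of at least 5 tested genes that share a symbol stem were tested with camera in the same way.

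Genes named in the text follow a rule. It took Med4, the 4 largest rises and 4 largest falls for each hairpin and for their difference, and the 10 largest rises and falls of the average among genes past the threshold with both hairpins. These needed a mean CPM of at least 5, groups that do not overlap and a symbol that is not a clone or predicted name. From each list it took up to 4 members with the smallest averaged adjusted p, and Mediator could be described in full. Ptprc, Tyrobp, Pecam1, Polr2b and Syn3 were named after their values were seen. A few genes that the rule takes are not reported here.

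Alternatives were DESeq2 1.42.0 (Wald test), its size factors or upper-quartile factors in edgeR, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, fits of only the libraries compared (with both hairpins pooled as 1 group for the average), the replicate number as a block, stricter thresholds and leaving out each library. Removing the GC and length trend, removing the local chromosomal shift (median of 25 tested neighbours on each side) and leaving out mitochondrial genes were added after seeing the data. Control sharing between the hairpins was simulated by drawing all 9 libraries from the NTC proportions with the fitted dispersions, 20 times.

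The steps were tested on simulated counts with known changes over 13996 genes. For shMed4 #1 against NTC, 84.5% of genes changed 2-fold and 76.0% of those changed 1.5-fold were recovered, with 9 false calls. For shMed4 #4, 74.0% of genes changed 1.5-fold were recovered, with 2 false calls. For the average it was 80.2% of those changed 1.5-fold, with 12 false calls. For the difference between hairpins, 85.6% of genes changed 2-fold were recovered, with 8 false calls. Camera found a list moved by 0.3 and passed 0 others of the 29. Simulated genes were drawn independently, so this does not test lists whose genes are correlated. In the tests of single genes at most 97 genes were changed by each fold. Recovery, false calls and scaling under changes as broad as those found here were therefore not tested.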

Results

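D2A1-d is a mouse breast carcinoma cell line used as a model of metastatic dormancy, the state in which disseminated tumour cells persist without growing out. Cells carried a non-targeting control hairpin (NTC) or 1 of 2 short hairpin RNAs against Med4, called shMed4 #1 and shMed4 #4. Med4 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Total RNA was sequenced from 9 libraries, with 3 libraries numbered as biological replicates in each of the 3 groups. The libraries held between 7572114 and 8582235 reads assigned to genes. The labels do not say whether the replicates were transduced or only grown separately, so p-values measure the spread between these libraries. The design asks which transcripts change when Med4 is depleted, and whether the hairpins agree.

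Med4 (ENSMUSG00000022109.6, chromosome 14, 73510025 to 73518849 in GRCm38, protein-coding) was lower in all 6 knockdown libraries than in all 3 NTC libraries. NTC libraries held 236, 216 and 204 Med4 reads, shMed4 #1 libraries 40, 35 and 38, and shMed4 #4 libraries 66, 60 and 50. The mean level was 27.4 ± 2.2 CPM (read counts scaled to a common library size) in NTC, 4.53 ± 0.39 with shMed4 #1 and 7.21 ± 0.98 with shMed4 #4 (SD, n = 3 each). The log2 fold change was -2.59 with shMed4 #1 (SE 0.14, edgeR adjusted p = 3.92e-18), which leaves 16.6% of the NTC level. With shMed4 #4 it was -1.92 (SE 0.13, edgeR adjusted p = 8.44e-16), which leaves 26.3%. Med4 was higher with shMed4 #4 than with shMed4 #1 by a log2 difference of 0.67 (SE 0.18, edgeR adjusted p = 0.00401).

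**Figure D1:**
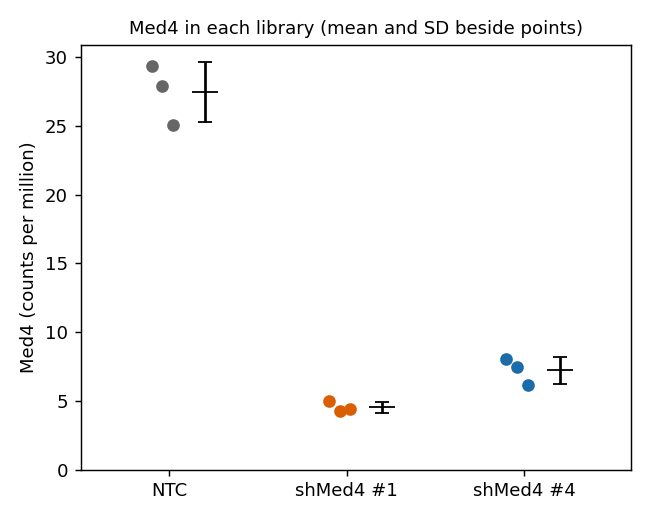
Med4 in CPM for each of the 9 libraries (points, by group), with the group mean and SD beside them. The NTC libraries lie between 25.04 and 29.35, above the shMed4 #1 libraries (4.24 to 4.97) and the shMed4 #4 libraries (6.13 to 8.05).

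Within groups, log expression correlated across genes at 0.991 to 0.993 between libraries. Between NTC and shMed4 #1 the correlation was 0.968 to 0.970, between NTC and shMed4 #4 it was 0.950 to 0.953, and between the hairpins 0.978 to 0.982. The first principal component held 62.2% of the variance and ordered the groups as NTC, shMed4 #1 and shMed4 #4. Mitochondrially encoded genes took 4.52 ± 0.08% of gene reads in NTC, 5.76 ± 0.32% with shMed4 #1 and 5.89 ± 0.13% with shMed4 #4 (SD, n = 3 each). The number of genes with a read was 21366 ± 56 in NTC, 21120 ± 139 with shMed4 #1 and 20474 ± 54 with shMed4 #4.

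With both hairpins averaged against NTC, Med4-depleted cells held more transcript for the luminal keratins Krt8 and Krt18, the adhesion receptors Itgb3 and Itgb1, 20 of 23 cholesterol synthesis genes and 12 of 14 mitochondrially encoded genes. They held less for the basement membrane collagens Col4a1 and Col4a2 and for 14 of 28 hypoxia and glycolysis genes. These 3 lists passed camera, with adjusted p = 0.0978, 0.255 and 0.397 in the order given with an estimated correlation. Of 14335 genes tested, 7640 passed an edgeR adjusted p of 0.05, with 3848 higher and 3792 lower in the knockdown. Of these, 1157 changed by at least 2-fold, 570 upward and 587 downward. Passing in the same direction with each hairpin were 4771 genes, 2501 higher and 2270 lower, of which 738 changed by at least 2-fold with each. The balance of directions depended on the scaling: with upper-quartile factors 3355 genes were higher and 4353 lower for the average, and 2162 higher and 2639 lower with each hairpin.

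Among genes with a mean of at least 5 CPM, the largest rises shared by both hairpins were mostly in genes that NTC cells barely expressed. Mgp (ENSMUSG00000030218.2, chromosome 6, 136872435 to 136875823), which encodes the calcification inhibitor matrix Gla protein, went from 0.375 ± 0.21 CPM in NTC to 10.8 ± 0.90 with shMed4 #1 and 8.47 ± 1.2 with shMed4 #4. This is an averaged log2 fold change of 4.61 (SE 0.28, edgeR adjusted p = 1.14e-16). It rests on 9 reads over the NTC libraries against 269 and 207 over the knockdown groups. Next came Etl4 with an averaged log2 fold change of 3.95, Adamts5, an aggrecan-cleaving protease, with 3.87, and Atp2b4, a plasma membrane calcium pump, with 3.78. Rbms3, an RNA-binding protein, rose by 3.65, Flt1, a receptor for VEGF, by 3.62, and Mum1l1 and Tesmin by 3.60 each. Cacng2, an auxiliary subunit of AMPA receptors, rose by 3.53 and As3mt, an arsenic methyltransferase, by 3.49. Cacng2 and Tesmin were among those with the most reads, with Cacng2 at 7.94 ± 1.3 CPM in NTC, 70.2 ± 8.5 with shMed4 #1 and 120 ± 5.8 with shMed4 #4.

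Under the same minimum, the largest shared falls were in Prl2c3 and Prl2c2, which encode the growth factor proliferin, with averaged log2 fold changes of -3.47 and -3.41. They are near-identical neighbours on chromosome 13, so the split of reads between them is uncertain. Cdh11, a mesenchymal cadherin, changed by -2.56, Dpep3 by -2.52, the atypical cadherin Fat4 by -2.41, the receptor tyrosine kinase Ephb2 by -2.40 and Prune2 by -2.21. Cdh11 and Dpep3 lie on a stretch of chromosome 8 where most genes were lower, with median shifts of their neighbours of -0.54 and -0.62 around Cdh11 and -0.53 and -0.64 around Dpep3. Col4a1 (chromosome 8, 11198423 to 11312826) went from 585 ± 6.4 CPM in NTC to 165 ± 3.0 with shMed4 #1 and 71.7 ± 4.5 with shMed4 #4, an averaged log2 fold change of -2.43 (SE 0.04, edgeR adjusted p = 1.37e-33). Its head-to-head neighbour Col4a2 (11312805 to 11449287) changed by -2.28, and the pair overlap on opposite strands over 0.295% of Col4a1.

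Of 11 measured mammary basal and luminal markers, 10 were higher and 1 lower (median log2 fold change 1.31, camera adjusted p = 6.59e-05, adjusted p = 0.0978 with an estimated correlation). Krt8, a luminal keratin, went from 3.93 ± 0.41 CPM in NTC to 19.2 ± 0.49 with shMed4 #1 and 53.9 ± 3.3 with shMed4 #4, an averaged log2 fold change of 3.03. Its partner Krt18 changed by 2.34, the smooth muscle and myoepithelial actin Acta2, also in the mesenchymal list, by 1.99 and the EGF receptor ligand Areg by 1.61. Krt8 and Krt18 are neighbours on chromosome 15, where the surrounding genes had median shifts of 0.18 and 0.31 with the hairpins. Of 10 measured epithelial genes, 6 rose and 2 fell (camera adjusted p = 0.015, adjusted p = 0.281 with an estimated correlation), with Jup (plakoglobin) up by 2.43 and Ovol1, at 8 reads over the NTC libraries and with 19.8% of its exon sequence shared with a gene on the other strand, by 2.66. Krt8 and Krt18 are in this list too and are among its rises, so the epithelial and mammary results are not independent. The lists held 28 epithelial and 29 mammary genes, and the rest were not among the genes tested. The mesenchymal list did not pass (5 up, 8 down of 18, camera adjusted p = 0.682), with Acta2 and Prrx1 (2.75) up and Cdh11 down.

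Matrix and adhesion genes changed in both directions. Of 34 structural matrix genes, 19 rose and 9 fell (camera adjusted p = 0.00591, adjusted p = 0.426 with an estimated correlation). Col6a3, a chain of beaded-filament collagen, rose by 2.69 and the fibril-associated collagen Col12a1 by 1.93, against the fall of Col4a1 and Col4a2. Of 35 matrix-remodelling genes, 21 rose and 9 fell (camera adjusted p = 0.00476, adjusted p = 0.104 with an estimated correlation), including rises of Adam19 (3.21) and of the metalloprotease inhibitors Timp3 (1.38) and Timp1 (1.30). Timp1 lies on a stretch of the X chromosome where most genes were higher, and Timp3 shares 21.3% of its exon sequence with Syn3 on the other strand. Integrins and focal adhesion genes rose more often than they fell, with 22 up and 8 down of 34 (camera adjusted p = 0.00384, adjusted p = 0.0978 with an estimated correlation). Itgb3, the beta chain of the vitronectin receptor, went from 6.90 ± 0.56 CPM in NTC to 42.8 ± 3.7 with shMed4 #1 and 55.1 ± 2.4 with shMed4 #4, a log2 fold change of 2.81. Itgb1, whose neighbours on distal chromosome 8 had median shifts of 0.20 and 0.42, changed by 0.80, Itga6, a laminin receptor chain, by 1.01 and the focal adhesion protein Zyx by 0.54.

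Of 23 cholesterol synthesis genes, 20 rose and 0 fell (median 0.49, camera adjusted p = 2.67e-08, adjusted p = 0.0978 with an estimated correlation). Examples are Hsd17b7 (1.37) and Dhcr7 (1.10). Of 30 genes of the unfolded protein and ATF4 response, 19 rose and 2 fell (camera adjusted p = 2.13e-06, adjusted p = 0.0978 with an estimated correlation), led by Pdia4 (0.85), Sdf2l1 (0.79), Creld2 (0.68) and Slc7a5 (0.62). Slc7a5 lies on distal chromosome 8, where its neighbours had median shifts of 0.19 and 0.30. Hypoxia and glycolysis genes fell on balance, with 7 up and 14 down of 28 (camera adjusted p = 0.0337, adjusted p = 0.397 with an estimated correlation), among them Bnip3 (-1.03), Pdk1 (-0.77), Pfkl (-0.68) and Pgk1 (-0.67). Bnip3 shares 22.3% of its exon sequence with a gene on the other strand. Of 14 mitochondrially encoded genes, 12 rose and 0 fell (camera adjusted p = 2.13e-06, adjusted p = 0.255 with an estimated correlation). mt-Nd5 changed by 0.83, mt-Nd2 by 0.65 and mt-Nd4 by 0.51, beside the rise of the mitochondrial share of reads given above. mt-Nd6 (0.92) lies on the other strand from mt-Nd5, its neighbour, and shares only 2.7% of its exon sequence with it. The strand setting of the counting is not given, so reads from either strand may be counted for mt-Nd6. Nuclear genes of oxidative phosphorylation did not pass as a group (15 up, 6 down of 37, camera adjusted p = 0.299), nor did cytosolic ribosomal proteins (10 up, 14 down of 41, camera adjusted p = 0.609).

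Of 32 DNA replication genes, 22 rose and 2 fell (median 0.20, camera adjusted p = 0.000274, adjusted p = 0.293 with an estimated correlation), with Ccne1 at 0.77, Ccne2 at 0.60, Rrm1 at 0.45 and Mcm3 at 0.37. Of 30 mitotic genes, 15 rose and 3 fell (median 0.11, camera adjusted p = 0.00673, adjusted p = 0.379 with an estimated correlation), with Plk1 at 0.55, Espl1 at 0.45, Mad2l1 at 0.44 and Foxm1 at 0.40. Much of some of these rises was shared by neighbouring genes. Median shifts of neighbours with the hairpins were 0.21 and 0.41 around Espl1, which itself changed by 0.30 and 0.60. They were 0.14 and 0.29 around Mad2l1 (itself 0.34 and 0.53) and 0.13 and 0.25 around Mcm3 (itself 0.27 and 0.48). Among p53 targets and CDK inhibitors, 9 rose and 5 fell of 23 (camera adjusted p = 0.901). The members with the smallest p fell, namely Sesn1 (-1.04), the death receptor Fas (-0.78), Cdkn1b (-0.60) and Cdkn2c (-0.60). Cdkn2c did not pass with both hairpins pooled as 1 group (edgeR adjusted p = 0.0506). Of 21 dormancy-associated factors, 6 rose and 7 fell (camera adjusted p = 0.925), with Lifr at -2.14, Hbp1 at -0.71, Axl at -0.40 and Mapk14, the p38 kinase, at 0.33. Hbp1 and Ccne2 share 24.6% and 17.4% of their exon sequence with genes on the other strand that had more reads, so their counts are uncertain. For the average, replication-dependent histones were lower in 6 of 10 and higher in 0 (camera adjusted p = 0.0337, adjusted p = 0.19 with an estimated correlation), at no more than 11.5 CPM in any group. Without NTC replicate 3 the camera adjusted p of the histones was 0.0649. This fall came from shMed4 #4, as with shMed4 #1 alone 2 rose and 1 fell (median -0.32, camera adjusted p = 0.848).

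Immune gene lists passed in opposite directions. Of 31 interferon-stimulated genes, 18 rose and 3 fell (camera adjusted p = 0.00591, adjusted p = 0.424 with an estimated correlation), and of 19 MHC class I genes 4 rose and 13 fell (camera adjusted p = 0.00242, adjusted p = 0.0978 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, changed by -1.96, H2-D1 by -0.81, H2-Q4 by -0.69 and H2-K1 by -0.50. Nlrc5 lies on the lower stretch of chromosome 8, where its neighbours had median shifts of -0.55 and -0.73. H2 genes are close paralogs, and H2-Q4 shares 19.1% of its exon sequence with a gene on the other strand, so their individual counts are uncertain. Neither list passed with each hairpin. With shMed4 #1 alone 5 MHC class I genes rose (6 adjusted over the list alone) and 10 fell (median -0.21, camera adjusted p = 0.351, adjusted p = 0.49 with an estimated correlation), and interferon-stimulated genes did not pass with shMed4 #4. Both lists differed between the hairpins in the direct comparison.

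The remaining lists did not pass for the average. Counts of members up and down were 10 and 5 of 21 for the TGF-beta pathway (camera adjusted p = 0.135), 2 and 3 of 14 for the BMP pathway and Id genes (0.609), and 8 and 9 of 22 for YAP and TAZ targets (0.786). They were 15 and 6 of 29 for immediate-early genes (0.0901), 8 and 7 of 24 for cytokines and NF-kB targets (0.908), and 13 and 13 of 37 for heterochromatin and Polycomb factors (0.908). Immediate-early genes passed without NTC replicate 3 (camera adjusted p = 0.0428). Genes of these lists that passed one by one include Tgfb2 (1.23), Ltbp2 (-1.02), Id1 (-0.47), Fst (1.49), Ankrd1 (0.83), Nt5e (0.99), Dusp4 (1.41), Fosl2 (-0.72), Vcam1 (0.98), Ccl2 (-1.03), Ezh1 (-0.52) and Jarid2 (-0.66). The neighbours of Jarid2 had median shifts of -0.26 and -0.43 with the hairpins. Markers of other cell types were mostly low, though C3 stood at 804 ± 73 CPM and Pdgfra at 128 ± 4.4 CPM in NTC. Counts up and down were 1 and 5 of 7 measured leukocyte markers (camera adjusted p = 0.101), 2 and 0 of 3 endothelial markers (0.135) and 2 and 4 of 9 stromal fibroblast markers (0.449). Cd14 went from 120 ± 11 CPM in NTC to 76.8 ± 4.1 with shMed4 #1 and 75.4 ± 4.4 with shMed4 #4. S100a8 changed by -2.76, Lyz2 by -1.60, Pdgfra by -0.91 and C3 by -0.82. The markers that rose were Cd74 (2.48, 14 reads over the NTC libraries), Flt1 (3.62), Cdh5 (1.48), Has2 (0.96) and Fbln1 (0.92). All 9 libraries together held 12 reads of Ptprc, 7 of Tyrobp and 35 of Pecam1.

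Of 32 Mediator subunits other than Med4, 6 were higher and 7 lower (camera adjusted p = 0.845). Med30 rose by 0.93 and Med14 by 0.85; both lie in regions where neighbouring genes were higher, with median shifts of 0.29 and 0.42 around Med30 (chromosome 15) and 0.50 and 0.49 around Med14 (X). Ccnc (0.32), Med13l (0.29), Cdk8 (0.28) and Med21 (0.13) were the other members that rose. Med12l (-1.16, near 1 CPM), Med16 (-0.54), Med22 (-0.39), Cdk19 (-0.27), Med13 (-0.27), Med12 (-0.22) and Med23 (-0.18) were lower.

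Adjusted over the list alone, counts for the average were 20 up for interferon-stimulated genes, 8 down for histones, 5 up for MHC class I, 5 up for Mediator, 3 up for stromal fibroblast markers, 7 up for dormancy-associated factors and 14 down for heterochromatin factors. The other lists had the counts given. No list passed for the average when camera estimated the correlation between genes (0 of 29, lowest adjusted p = 0.0978), while 7 had an unadjusted p under 0.05. At the preset correlation 14 passed, and 21 passed the directional test fry, which asks whether the members move on balance and sets them against no other genes. The sign of the median, the mean and the camera test differed for the p53, YAP and TAZ, dormancy and heterochromatin lists.

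**Figure D2:**
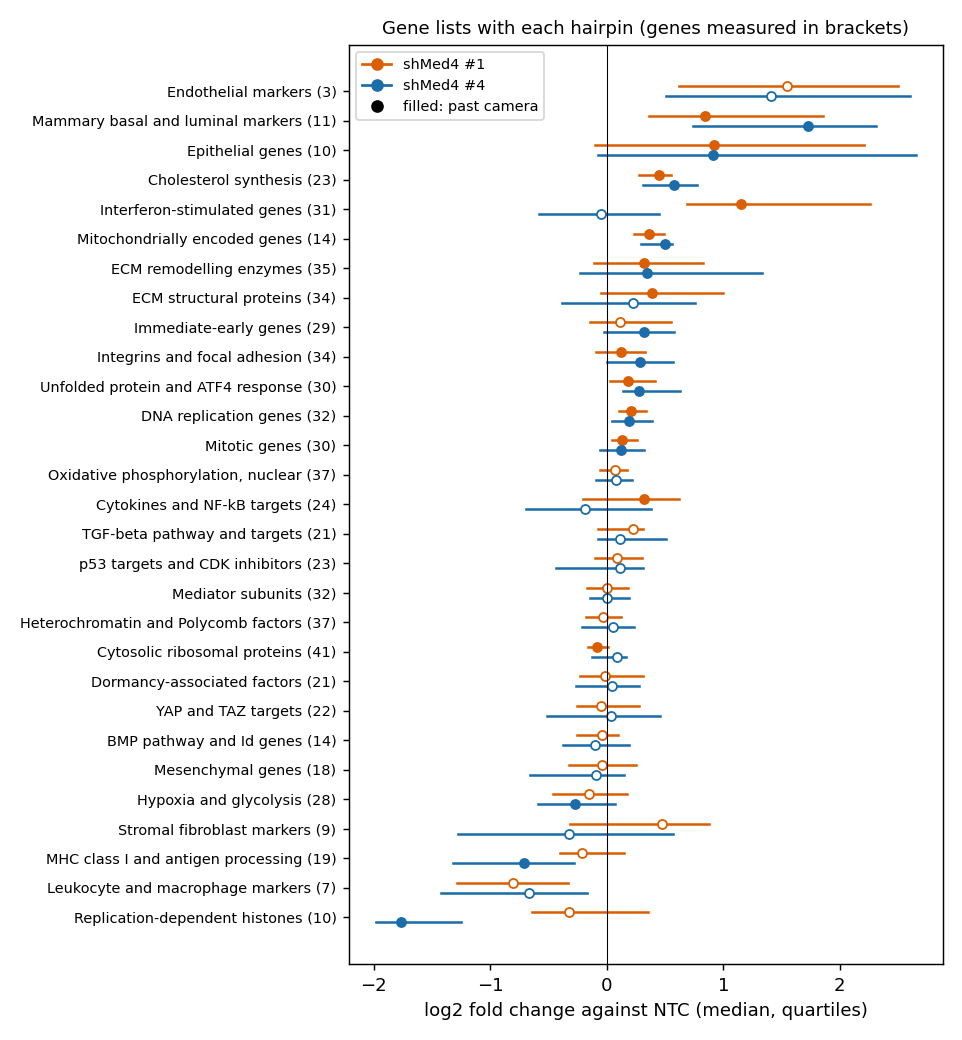
Median log2 fold change against NTC for the members of each of 29 gene lists (x axis), with lines from the lower to the upper quartile, for shMed4 #1 and shMed4 #4. Filled points passed camera. Interferon-stimulated genes have a median of 1.15 with shMed4 #1 and -0.0506 with shMed4 #4.

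With shMed4 #1, the list with the smallest camera p was that of interferon-stimulated genes, 25 up and 1 down of 31 (median 1.15, camera adjusted p = 3.47e-14, adjusted p = 0.117 with an estimated correlation). Oasl2, an interferon-induced antiviral protein, went from 4.81 ± 0.86 CPM to 25.1 ± 3.9, a log2 fold change of 2.38, the viral RNA sensor Ddx58 changed by 1.15 and the kinase Eif2ak2 by 1.10. Ifit2 was the member that fell (-0.46). With shMed4 #4 the values were 0.36 for Oasl2 (edgeR adjusted p = 0.123) and 0.11 for Ddx58 (0.22). Eif2ak2 rose with shMed4 #4 too (0.54, edgeR adjusted p = 2.86e-06), and Ifit2 fell (-1.29, edgeR adjusted p = 8.75e-14). In all, 5966 genes passed edgeR, 3132 higher and 2834 lower, of which 918 changed by at least 2-fold (562 up, 356 down). Among genes with a mean of at least 5 CPM, the largest rises were in Mgp (4.79), Atp2b4 (4.17), Adamts5 (3.88) and Etl4 (3.71), and the largest falls in Prl2c3 (-3.25), Prl2c2 (-2.72), Med4 (-2.59) and Col4a1 (-1.82).

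Camera passed 13 lists with shMed4 #1, 12 upward and 1 downward, and 0 with an estimated correlation (lowest adjusted p = 0.117, 6 at an unadjusted p under 0.05); fry passed 18. Cholesterol synthesis had 18 up and 0 down of 23, mitochondrially encoded genes 10 and 0 of 14, and mammary basal and luminal markers 7 and 1 of 11. DNA replication had 20 up and 1 down of 32, mitotic genes 13 and 0 of 30, the unfolded protein response 17 and 2 of 30, and epithelial genes 6 and 1 of 10. Structural matrix genes had 22 up and 6 down of 34, matrix remodelling 20 and 9 of 35, and integrins 15 and 6 of 34. Estimated-correlation adjusted p-values of these lists lay between 0.117 and 0.287. Integrins had a camera adjusted p of 0.0285, and of 0.0865 once the local chromosomal shift was removed. Cytokines and NF-kB targets (12 up, 6 down of 24, camera adjusted p = 0.0376, adjusted p = 0.338 with an estimated correlation) did not pass without NTC replicate 1 (0.0503), NTC replicate 2 (0.0511) or shMed4 #1 replicate 1 (0.0505). Cytosolic ribosomal proteins were the list that fell (3 up, 12 down of 41, camera adjusted p = 0.0161, adjusted p = 0.735 with an estimated correlation), which did not pass without NTC replicate 3 (0.15) or shMed4 #1 replicate 1 (0.067). Adjusted over the list alone, counts up were 27 for interferon-stimulated genes, 22 for DNA replication, 21 for matrix remodelling, 16 for integrins, 14 for mitotic genes, 13 for cytokines, 11 for mitochondrially encoded genes, 8 for basal and luminal markers and 2 for ribosomal proteins, and counts down 7 each for structural matrix genes and integrins. Hypoxia and glycolysis genes (7 up, 13 down of 28, camera adjusted p = 0.0566) passed without NTC replicate 2 (0.0326) or shMed4 #1 replicate 2 (0.0225), and with the GC and length trend (0.0363) or the local shift (0.00761) removed. Endothelial markers (2 up, 0 down of 3, camera adjusted p = 0.0777) passed with the local shift removed (0.0202), and leukocyte markers (1 up, 5 down of 7, camera adjusted p = 0.0617) without NTC replicate 1 (0.0344). The sign of the median, the mean and the test differed for the mesenchymal, BMP and dormancy lists.

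With shMed4 #4, 9 of 10 replication-dependent histones and 15 of 19 MHC class I genes were lower than in NTC, and Krt8 (3.77), Krt18 (2.70) and Itgb3 (2.99) were higher. In all, 7895 genes passed edgeR, 3988 higher and 3907 lower, of which 1585 changed by at least 2-fold (647 up, 938 down). Again with a mean of at least 5 CPM, and leaving out symbols taken from clones, the largest rises were in Mgp (4.44), Etl4 (4.19), Tesmin (4.10) and Rbms3 (3.96), and the largest falls in Prl2c2 (-4.09), Prl2c3 (-3.69), Xist (-3.64) and Prune2 (-3.49). Of 19 MHC class I genes, 15 fell and 4 rose (median -0.71, camera adjusted p = 2.98e-05, adjusted p = 0.057 with an estimated correlation), with H2-D1 at -1.16 and Nlrc5 at -2.44. Of 10 histone genes 9 fell and 0 rose (median -1.77, camera adjusted p = 0.00391, adjusted p = 0.0689 with an estimated correlation). These transcripts mostly lack a poly(A) tail and stood at a few CPM, such as Hist2h4 at 3.25 CPM in NTC and 0.572 with shMed4 #4. Interferon-stimulated genes did not pass as a group (4 up, 10 down of 31, camera adjusted p = 0.369).

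Camera passed 13 lists with shMed4 #4, 10 upward and 3 downward, and 0 with an estimated correlation (lowest adjusted p = 0.057, 7 at an unadjusted p under 0.05); fry passed 23. Cholesterol synthesis had 20 up and 0 down of 23, the unfolded protein response 22 and 3 of 30, mitochondrially encoded genes 11 and 0 of 14, and integrins 21 and 7 of 34. Mammary basal and luminal markers had 9 up and 0 down of 11, epithelial genes 6 and 2 of 10, matrix remodelling 21 and 8 of 35, and DNA replication 18 and 2 of 32. Hypoxia and glycolysis genes fell (7 up, 14 down of 28, camera adjusted p = 0.026, adjusted p = 0.355 with an estimated correlation). Estimated-correlation adjusted p-values of the upward lists lay between 0.057 and 0.481. Immediate-early genes (16 up, 5 down of 29, camera adjusted p = 0.0398) did not pass without NTC replicate 1 (0.0784) or NTC replicate 2 (0.0545), nor with the GC and length trend removed (0.0627). Mitotic genes (15 up, 3 down of 30, camera adjusted p = 0.0398) did not pass without NTC replicate 3 (0.14). Structural matrix genes had 16 up and 10 down of 34 (camera adjusted p = 0.0598). They passed without NTC replicate 2 (0.0285), shMed4 #1 replicate 1 (0.0467) or 2 (0.0474), or shMed4 #4 replicate 1 (0.0226) or 3 (0.0379), and with the local chromosomal shift removed (0.00647). Adjusted over the list alone, counts up were 23 each for integrins and the unfolded protein response and 12 for mitochondrially encoded genes. The sign of the median, the mean and the test differed for the p53, YAP and TAZ, dormancy and heterochromatin lists.

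The log2 fold changes of both hairpins correlated across genes at 0.798, with a covariance of 0.341. Both share the NTC libraries, and genes are not independent replicates. In 20 simulations of unchanged groups against shared controls, the correlation was 0.508 (range 0.485 to 0.528) and the covariance 0.0131, with 0 genes passing with both hairpins. The observed covariance exceeded the simulated one by 0.327. Independent lists of these sizes would share 871.3 genes upward and 772.4 downward, against 2501 and 2270 observed. With 3 control libraries no split leaves 2 in each part, so some of the excess may come from the shared controls. A further 1082 genes passed with shMed4 #1 alone and 3011 with shMed4 #4 alone, which is not itself a test of a difference. Of the 4771 shared genes, 3632 (76.1%) changed more with shMed4 #4, with a median absolute log2 fold change of 0.543 against 0.411 with shMed4 #1.

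**Figure D3:**
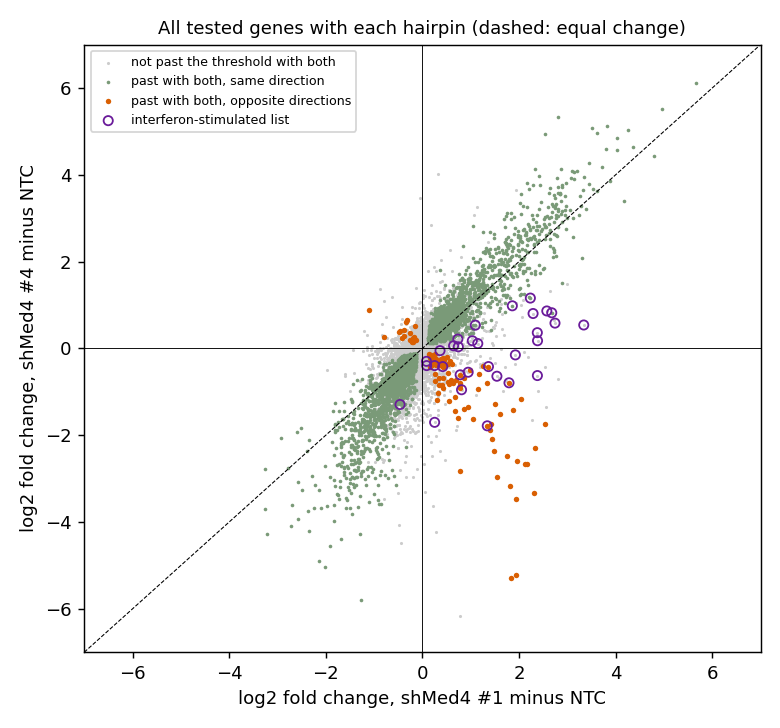
Log2 fold change against NTC with shMed4 #1 (x axis) and shMed4 #4 (y axis) for each of 14335 tested genes. Green points are the 4771 genes past the threshold in the same direction with both hairpins, orange points the 113 past it in opposite directions, and circles the interferon-stimulated list.

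Compared directly, shMed4 #4 cells held less transcript than shMed4 #1 cells for all 31 measured interferon-stimulated genes, and more for Krt8, Krt18 and Areg. In all 4017 genes differed by edgeR, 2029 higher and 1988 lower with shMed4 #4, of which 479 differed by at least 2-fold (81 up, 398 down). The interferon-stimulated list had a median log2 difference of -1.49 (camera adjusted p = 3.81e-30, adjusted p = 0.028 with an estimated correlation). Gbp4 and Gbp9, interferon-induced GTPases of 1 cluster on chromosome 5, had log2 differences of -3.84 and -3.61. Gbp4 went from 5.93 ± 0.27 CPM in NTC to 16.7 ± 1.6 with shMed4 #1 and 1.15 ± 0.95 with shMed4 #4. Gbp genes are close paralogs that overlap on the genome, so their individual counts are uncertain. MHC class I genes were lower in 14 and higher in 1 of 19 (median -0.70, adjusted p = 0.0187 with an estimated correlation). Histones were lower in 9 and higher in 0 of 10 (median -1.47, adjusted p = 0.028 with an estimated correlation). Of 34 integrin and focal adhesion genes, 13 were higher and 3 lower (median 0.12, adjusted p = 0.033 with an estimated correlation).

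Igfbp7, a secreted insulin-like growth factor binding protein, had the largest difference among genes with a mean of at least 5 CPM, at -4.23 (SE 0.20, edgeR adjusted p = 8.12e-19). It stood at 6.45 ± 0.69 CPM in NTC, 21.7 ± 1.7 with shMed4 #1 and 1.14 ± 0.49 with shMed4 #4. It shares exon sequence with Polr2b on the other strand over 7.03% of its length. Polr2b had 8744 reads over all libraries against 724 for Igfbp7, so some of the reads of Igfbp7 are uncertain. Xist, the RNA that coats the inactive X chromosome, was at 43.5 ± 4.7 CPM in NTC, 50.8 ± 8.8 with shMed4 #1 and 3.48 ± 1.3 with shMed4 #4, a log2 difference of -3.86. Areg (1.52), Krt8 (1.49), Dynap (1.45) and Tbc1d16 (1.31) had the largest differences upward under the same minimum, leaving out symbols taken from clones. Areg went from 9.13 ± 1.3 CPM in NTC to 16.4 ± 2.7 with shMed4 #1 and 47.2 ± 0.68 with shMed4 #4.

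Camera passed 10 lists for this difference, 6 upward and 4 downward, of which 4 passed with an estimated correlation. The 6 others were cytokines and NF-kB targets (2 up, 13 down of 24, adjusted p = 0.0776 with an estimated correlation), mammary basal and luminal markers (5 and 1 of 11, 0.0776), the unfolded protein response (16 and 3 of 30, 0.0819), cholesterol synthesis (8 and 0 of 23, 0.228), immediate-early genes (9 and 4 of 29, 0.452) and ribosomal proteins (18 and 1 of 41, 0.496). Mitochondrially encoded genes did not pass (5 up, 0 down of 14, camera adjusted p = 0.0676). They passed without shMed4 #1 replicate 1 (0.000203), shMed4 #4 replicate 2 (0.0348) or shMed4 #4 replicate 3 (0.0152), and with the GC and length trend removed (0.000677), the local shift removed (0.0494) or the replicate number as a block (0.0439). Immediate-early genes did not pass with the GC and length trend removed (0.0648). Without 1 library, structural matrix genes (shMed4 #4 replicate 2, 0.0444), epithelial genes (shMed4 #4 replicate 3, 0.0254), and p53 targets and stromal markers (shMed4 #1 replicate 1, 0.046 each) passed. Structural matrix genes and stromal markers also passed with the GC and length trend removed (0.048 each), and stromal markers (0.0282) and hypoxia and glycolysis genes (0.01) with the local shift removed. Adjusted over the list alone, counts were 16 down for MHC class I, 22 up for ribosomal proteins, 19 up for the unfolded protein response, 10 up for cholesterol synthesis, 3 up and 14 down for cytokines, and 12 up and 5 down for immediate-early genes. The sign of the median, the mean and the test differed for the DNA replication, p53, dormancy, heterochromatin, nuclear oxidative phosphorylation and endothelial lists.

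Changes also followed chromosome position, on stretches picked after the medians along the genome were seen. Over the first 60 Mb of the X chromosome (131 tested genes), the median log2 fold change was 0.47 with shMed4 #1 and 0.58 with shMed4 #4, and 88.5% and 89.3% of genes were higher than in NTC. Between 75 and 110 Mb of chromosome 8 (303 genes), the medians were -0.43 and -0.52, with 87.5% and 85.1% lower. Distal to this, the 159 genes from 110 Mb to the end had medians of 0.19 and 0.36. On chromosome 3 between 140 and 160 Mb (60 genes) the medians were -0.22 and -0.55. Of 134 windows of 20 Mb with at least 30 tested genes, 5 exceeded the largest median of 1000 shuffles of gene positions with both hairpins in the same direction. They were those of X from 0 to 60 Mb, of chromosome 8 from 80 to 100 Mb and of chromosome 6 from 0 to 20 Mb (medians 0.339 and 0.462). None lay on the distal stretch of chromosome 8 or on that of chromosome 3, where the window passed with shMed4 #4 only. Medians between replicates of a group were at most 0.142 in size. Genes named in the text that lie on the stretches described include Cdh11, Dpep3, Nlrc5, Smad1, Cdh5, Timp1, Med14, Itgb1, Slc7a5 and Rpl13. Of these, Cdh5 rose although its neighbours had median shifts of -0.56 and -0.65. With the median of 50 neighbours removed, an alternative chosen after seeing the data, 3785 genes passed with both hairpins, of which 3011 were among the 4771.

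**Figure D4:**
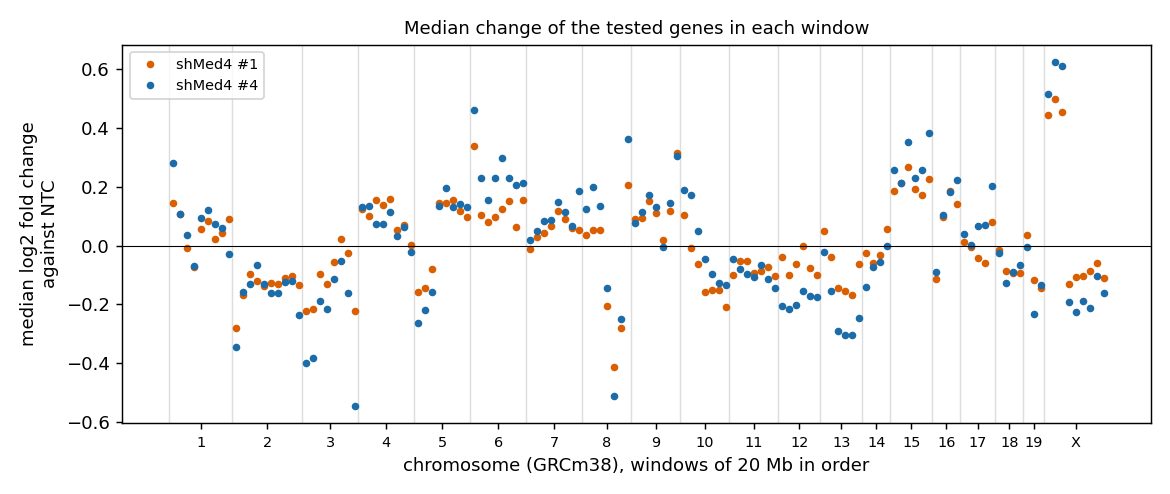
Median log2 fold change against NTC (y axis) of the tested genes in each of 134 windows of 20 Mb along the mouse chromosomes (x axis), for shMed4 #1 and shMed4 #4. The windows at the start of X lie between 0.445 and 0.626, and the window of chromosome 8 from 80 Mb lies at -0.412 and -0.513.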

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

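The tests here that were chosen after the result was seen are those of genes with opposite directions, of interferon-stimulated genes above a CPM minimum in each group, of leukocyte markers, of the local chromosomal shift removed and of other splits of the libraries.

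Differences between the hairpins were tested directly. Med4 was higher with shMed4 #4 by a log2 difference of 0.67, and 113 genes passed the threshold in opposite directions, 91 of them up with shMed4 #1 and down with shMed4 #4. Median log2 differences of the lists past camera, shMed4 #4 minus shMed4 #1, were -1.49 for interferon-stimulated genes, -1.47 for histones, -0.70 for MHC class I and -0.37 for cytokines and NF-kB targets. They were 0.56 for mammary basal and luminal markers, 0.16 for the unfolded protein response, 0.15 for cholesterol synthesis, 0.14 for ribosomal proteins, 0.13 for immediate-early genes and 0.12 for integrins. With an estimated correlation, interferon-stimulated genes, histones, MHC class I and integrins passed and the other 6 lists did not (adjusted p between 0.0776 and 0.496). Named genes that rose with shMed4 #1 and fell with shMed4 #4 were Igfbp7 (-4.23), Gbp4 (-3.84) and Gbp9 (-3.61).

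Changes were larger with shMed4 #4 although less Med4 remained with shMed4 #1. The sequencing depth is argued against: with all libraries thinned to the size of the smallest, the excess of calls with shMed4 #4 was 1915 genes, 99.3% of the 1929 at full depth. Effects specific to a hairpin cannot be told apart from other differences between the cell populations, since hairpin and population coincide; the 113 genes with opposite directions would come from either, and matches of the hairpins to other transcripts were not analysed here. MED4 protein was not analysed here, and a biological difference between the populations stays open and was not tested.

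Of 31 interferon-stimulated genes, 25 were higher with shMed4 #1 than with NTC, and all 31 were lower with shMed4 #4 than with shMed4 #1. The block shifts along chromosomes are argued against, since the list median of the difference was -1.46 after the local shift was removed, against -1.49 before. Counts near the floor are argued against as the whole cause, since the 15 members with a mean CPM of at least 5 in each group had a median of -0.71 (quartiles -0.95 and -0.54), smaller in size than that of the whole list. Leukocytes in the shMed4 #1 cultures are argued against, since 0 of 7 measured leukocyte markers were past the threshold and lower in edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2) and all libraries together held 12 Ptprc reads. An innate immune response to 1 hairpin, or a loss of interferon signalling with the other, is an open hypothesis that these groups do not test.

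Other splits of the libraries were counted. For shMed4 #1 against NTC (5966 genes), shMed4 #4 against NTC (7895) and the hairpins against each other (4017), the real split was 1 of 10 and the highest other split gave 0 genes, and 10 splits are too few for a share under 0.05. For the average, 1 of 100 splits, the real one, gave as many as 7640 genes (highest other 5602). The same held for the 4771 shared genes (highest other 3709). Splits that mix the groups widen the spread within them, so this shows that libraries cluster by group. It cannot tell an effect of Med4 from another difference between the populations, since knockdown and population coincide. For the lists the real split gave 14 and the highest other 13, which sets them little apart, and 0 lists passed with an estimated correlation. Which splits gave the high other counts was not examined.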

How the results depend on the processing

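The tests chosen after the result was seen are those with the GC and length trend removed, with the local chromosomal shift removed and without mitochondrial genes. Med4 was lower and past the threshold under each alternative. Leaving out 1 library gave 5159 to 6145 genes for shMed4 #1, 7203 to 8183 for shMed4 #4, 6719 to 7803 for the average, 3262 to 4129 for the difference, 4130 to 4656 shared and 14 lists each time. Med4 ranged from -2.32 to -2.20 for the average, from -2.66 to -2.54 with shMed4 #1 and from -2.00 to -1.81 with shMed4 #4. Requiring a log2 fold change of at least 1 gave 918, 1585, 1157, 479 and 738 genes in the same order, and an adjusted p under 0.01 gave 2573 for the difference, both stricter by construction. No list (0) passed for the average with an estimated correlation, against 14 by camera and 21 by fry. The estimated correlation lay above the preset 0.01 for some lists, such as mitochondrially encoded genes (0.42). For integrins it lay below (-0.016), yet the camera adjusted p went from 0.00384 to 0.0978. A higher correlation between members is therefore not the whole cause for integrins, and the cause was not tested further. Upper-quartile factors turned the balance of higher and lower genes in each comparison, to 2767 and 3240 for shMed4 #1, 3484 and 4452 for shMed4 #4, 3355 and 4353 for the average, 1817 and 2138 for the difference and 2162 and 2639 shared, with the median of all genes at -0.0584 or nearer to 0. DESeq2 gave 4516, 6659, 6325, 2728 and 3638 genes, within 1.5 times. The replicate numbers did not pair the libraries (same-number correlations -0.0586 to 0.0352, best with the own number in 4 of 18); with the replicate block the counts were 5828, 7807, 7537, 3859 and 4677. With the local chromosomal shift removed the counts were 4946, 7099, 6634, 3698 and 3785; there Atp5c1 changed sign to 0.054 and Rpl13 to -0.097, neither past the threshold, because their neighbours shifted as much. Cbx5, Ndufa4, Ndufb5 and Smad1 no longer passed there. With both hairpins pooled as 1 group, which adds the difference between hairpins to the spread, Cdkn2c, Hist1h1d and Hist2h4 no longer passed. Depth limits the genes at a few CPM, such as the histones.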

Other observations

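The tests here that were chosen after the result was seen are those of chance placement, of the GC and length trend removed and of the correlation of window medians. The stretches were picked from the medians, and the families of related gene symbols were not fixed in advance.

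Families of genes that share a symbol stem were tested with camera (358 families). All 5 measured genes with the Irx stem, 4 homeobox transcription factors and 1 antisense transcript, were lower with each hairpin (median -0.64 with shMed4 #1, camera adjusted p = 0.0457, and -0.92 with shMed4 #4, camera adjusted p = 0.0452). On chromosome 8, 3 of them lie on the lower stretch, where their neighbours had median shifts of -0.58 to -0.56 and -0.87 to -0.84, so their fall stands little apart from that of the stretch. The other 2, on chromosome 13, fell by more than their neighbours (-0.13 and -0.10 with shMed4 #1, -0.27 and -0.22 with shMed4 #4). Apol genes rose with shMed4 #1, 5 up and 0 down of 7 (median 2.10, camera adjusted p = 0.00175). The 7 Cxcl chemokine genes were lower with shMed4 #4 than with shMed4 #1 in 6 cases and higher in 0 (median -0.88, camera adjusted p = 1.72e-07). Parp genes were lower in 7 and higher in 0 of 12 (camera adjusted p = 0.00312), and Cct chaperonin genes higher in 4 and lower in 0 of 7 (camera adjusted p = 0.0306). Whether the changes of Apol, Cxcl and Parp genes stand apart from those of the interferon-stimulated list was not tested.

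Xist was at 1041 reads over the NTC libraries, 1268 with shMed4 #1 and 85 with shMed4 #4. The 262 tested genes of X beyond 65 Mb had medians of -0.11 with shMed4 #1 and -0.17 with shMed4 #4. Those of its first 60 Mb (131 genes) had medians of 0.47 and 0.58.

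Block shifts along chromosomes were shared by the hairpins. Chance placement of changed genes is argued against, since 5 windows lay past 1000 shuffles with both hairpins, and GC content or gene length bias too, since 5 windows also did after that trend was removed. A difference in DNA copy number between the NTC cells and both knockdown populations is a candidate explanation for the stretches on X and chromosome 8. Each expression tercile there shifted the same way, the smallest tercile median being 59.8% of the whole. The terciles also went the same way on the stretch of chromosome 3, on 13 and 15, distal 8 and X beyond 65 Mb. The smallest of these was 41.7% of the whole, on chromosome 15. But on chromosome 6 the low-expression tercile went the other way (-0.0487 and -0.112). On every stretch but distal 8 the low-expression tercile had the lowest median of the terciles with both hairpins. A dependence of the changes on expression level was not removed, so the signs of the terciles do not by themselves decide on copy number. A domain-wide effect of Med4 depletion cannot be told apart from a difference in copy number. The window medians of the hairpins correlate at 0.928 either way, and knockdown coincides with the cell population. DNA was not analysed here.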
